A study of Arabidopsis thaliana with 4 samples.

How the data were processed

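The study measured transcripts in roots of Arabidopsis thaliana with one-colour Affymetrix arrays and biotin-labelled RNA. The groups were taken from the samples' titles and treatment descriptions: 2 arrays of plants inoculated with Gigaspora rosea and 2 of mock-treated plants, with replicate numbers 1 and 2 from the titles. The values analysed are the intensity values deposited by the authors, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes, which give no version. MAS5, as the algorithm is generally described, combines the probes of a set into a signal on a linear scale and scales each array. The deposited values were positive and linear, and the mean of each array without its lowest and highest 2% of probe sets was 100.0. How the arrays were scanned, and any filter beyond MAS5, is not given in the sources used here. MAS5 signals of dim probe sets are noisy on a log scale, and the scaling removes differences in total RNA between arrays. No array lacked values, and 0 columns of other samples were present.

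The table holds 22810 probe sets, of which 64 are controls and were left out of all tests. Of the other 22746, the probe annotation named 1 gene for 13513 and several genes for 503. The remaining 8730 are not listed there and are unnamed here, and many known genes are among them for this reason. Gene symbols were updated through the gene identifiers in a table of the TAIR10.1 assembly, which matched 7362 of the 7387 tested probe sets with 1 gene. These 7387 stand for 7341 genes. No coordinates are given, since the files do not name the genome build behind the probe sets.

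Signals below 1 were set to 1 and all were taken to log2, with no further normalization. Probe sets with a mean log2 signal under the 40th percentile, which lay at a signal of 29.3, were not tested. The signals of the 4 arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with treatment as the only term, and p-values were adjusted by Benjamini-Hochberg over 13648 probe sets at a threshold of 0.05. Positive values mean higher after inoculation. With 2 arrays in each group, an exact permutation test of a single gene has 3 divisions of the arrays and cannot reach 0.05, so all tests borrow the spread from other genes. Gene groups with at least 3 tested members were tested with camera at a preset correlation of 0.01, and 3 of the 20 groups had that many. Each gene was represented by its brightest probe set.

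The test, the filter, the gene groups, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 genes per direction with the smallest p, among tested probe sets with 1 gene, at least 1.5-fold apart and with both arrays of one group above both of the other. It also took the 2 highest and 2 lowest tested members of each group and allowed all members of the symbiosis group. The groups were symbiosis, phosphate, chitin and defence, salicylate, jasmonate and ethylene, indolic, phenylpropanoid, nitrogen, iron, sulfur, sugar, auxin and cytokinin, touch with heat and drought, clock, root hair, root tip meristem, xylem, endodermis and suberin, photosynthesis, and reference genes. The 13 gene families and the genes set apart by replicate number in the closing observations were chosen after the data had been seen.

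Alternatives were quantile normalization, centring on the median, an offset of 9.42 added to the signals (the 20th percentile), no filter, a filter at the 60th percentile, eBayes without the trend or with the robust option, an adjusted p threshold of 0.1, a gap of 2-fold, camera with an estimated correlation, fry, the replicate number as a block, and each array left out in turn. The fits were tested on 20 simulated data sets for inoculated against mock over 13648 probe sets, with 200 of them changed in each and the measured differences between replicate numbers kept. The limma fit without a block found 0% of 2-fold, 0.2% of 2.83-fold, 12% of 4-fold and 65.5% of 8-fold changes, with 0.05 false calls per data set. The fit with the replicate number as a block found 69.3%, 96.7%, 99.6% and 100% of these sizes, with 26.9 false calls per data set, which is more than the adjusted threshold allows for the calls it makes. Camera found 20 of 20 simulated lists of 15 members shifted by 0.8 on the log2 scale, and gave p under 0.05 for 3 of 60 unshifted lists. The lists tested here had 3, 4 and 6 members, for which recovery was not simulated.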

Results

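Transcript levels were measured on 4 one-colour Affymetrix arrays, each hybridised with labelled RNA from the whole root system of Arabidopsis thaliana. The plants were grown in a sand and clay substrate at 0.1 mM phosphate. On 2 arrays the plants had received germinated spores of Gigaspora rosea, a soil fungus that forms arbuscular mycorrhiza with the roots of many land plants. On the other 2 arrays the plants had received moist sterile filter paper in place of the spores (mock). Arabidopsis is a textbook example of a plant that does not form this symbiosis, and the series title asks whether it holds the signalling pathways for it. Each group has an array of replicate 1 and an array of replicate 2. The median signal of an array was 42.99 and 46.12 in the inoculated group and 47.88 and 46.62 in the mock group, and 13648 of 22746 plant probe sets were bright enough to be tested. The number of arrays and the spread between them limit the precision. With treatment as the only term, the median 95% interval of a log2 difference reached 0.66 to either side, a 1.58-fold change. Nothing in the labels says that the replicates came from separate plants or cultures, so the p-values measure only the spread between these arrays, which may be technical.

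The first comparison asked which root transcripts differ after inoculation. No gene passed the test in either direction. Among genes with lower signals after inoculation, the largest mean log2 difference of those named by rank was in AT1G67300, a predicted plastidic glucose transporter, with 117 ± 27.9 (SD, n = 2 here and below) in inoculated and 234 ± 66.5 in mock roots. AT5G49900, a protein of the glucosylceramidase family, was at 157 ± 36.3 against 317 ± 122, and HHP2, a heptahelical membrane protein, at 193 ± 7.79 against 301 ± 56.8. Among genes with higher signals, AT4G28240, a protein of the wound-responsive family, was the brightest, with 914 ± 458 in inoculated and 497 ± 76.5 in mock roots. AT1G14200, a RING finger protein, was at 120 ± 19.5 against 72.7 ± 7.90.

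In the test with limma, 0 of 13648 probe sets reached an adjusted p of 0.05, and the lowest adjusted p was 0.9999. An unadjusted p under 0.05 was reached by 34 probe sets, of which 6 were higher and 28 lower after inoculation. Arrays that varied independently of each other would give 682, a condition that the third comparison below does not support. After quantile normalization 13 were higher and 17 lower, and after median centring 9 and 20. With the replicate number as a block, a fit that made too many false calls on simulated data, 233 were higher and 201 lower. Both arrays of one group lay above both arrays of the other in 2303 probe sets (16.9%). The 33.3% that independently varying arrays would give rests on the same condition. A large difference between replicate numbers lowers this share by itself, so the comparison of the shares says nothing about inoculation. A gap of at least 1.5-fold between the groups was found in 5 probe sets, and a gap of 2-fold in 0. Of these 5, the genes AT5G42765 (45.7 and 47.3 in inoculated, 26 and 30.3 in mock roots) and AT3G07860 (21.0 and 23.4 in inoculated, 38.7 and 48.4 in mock roots) are named in the probe table, and the other 3, all lower after inoculation, are unnamed there. The counts at an unadjusted p under 0.05 and with a 1.5-fold gap depended on the filter for dim probe sets, with 389 and 385 probe sets when none were removed. Leaving out an array also moved the first count. In such a fit 1 array stands for a group, and part of the difference between replicate numbers enters that of inoculation.

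The 12 genes per direction with the smallest p among those at least 1.5-fold apart were named by a rule set before the data were examined, and all of them failed the adjusted test. Their folds lay between 1.51 and 1.99. Among the 12 lower ones, AT1G67300 differed by a log2 value of -0.99 (SE 0.30, 95% interval -1.74 to -0.24). Log2 differences of -0.97 (SE 0.34) and -0.77 (SE 0.26) were measured for AT5G49900 and for AT4G36970, which belongs to the remorin family of membrane-associated proteins. The nitrate and peptide transporter family member NPF6.2 (AT2G26690) differed by -0.61 (SE 0.25), with 93.2 and 93.3 in inoculated against 168 and 120 in mock roots. AT1G63100, a GRAS family transcription factor, was at 42.1 and 49.2 against 70.2 and 66.8. AT5G19730, of the pectin methylesterase family, was at 30.3 and 34.5 against 51.2 and 57.4, and the protein kinase AT1G72540 at 24.0 and 31.8 against 47.4 and 44.8. The others on the lower side were AT3G07860, AT2G47410, HHP2 (AT4G30850), AT3G50685 and AT5G01030.

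Among the 12 higher genes, the log2 difference was 0.72 (SE 0.24, 95% interval 0.11 to 1.32) for AT1G14200 and 0.79 (SE 0.38, 95% interval -0.16 to 1.75) for AT4G28240. The cytochrome P450 gene CYP78A9 (AT3G61880) was at 72.5 and 48.8 in inoculated and 42.6 and 33.0 in mock roots, a log2 difference of 0.66 (SE 0.31). AT3G61400, an oxoglutarate-dependent dioxygenase, was at 52.5 and 41.9 against 37.0 and 25.7. AT1G74780, a transporter-like protein of the nodulin-like family, was at 80 and 71.7 against 69.0 and 35.7. AT4G01910, which carries cysteine- and histidine-rich domains, was at 103 and 93.3 against 44.0 and 91.3. The remaining ones were AT5G42765, AT4G23930, AT1G55990, AT3G07350, AT5G55210 and AT1G69160. With an array left out, the log2 difference ranged from 0.26 to 1.33 for AT4G28240, from 0.10 to 1.16 for AT4G01910, from 0.13 to 1.08 for AT1G74780, from 0.27 to 1.23 for AT1G69160 and from 0.38 to 0.95 for CYP78A9. Among the lower genes it ranged from -1.38 to -0.57 for AT5G49900, from -1.30 to -0.55 for AT2G47410, from -1.28 to -0.70 for AT1G67300 and from -0.85 to -0.37 for NPF6.2. These ranges also take in part of the difference between replicate numbers, since 1 array then stands for a group. The intervals are those of single genes and do not allow for the choice of these 24 from all tested probe sets.

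**Figure D1:**
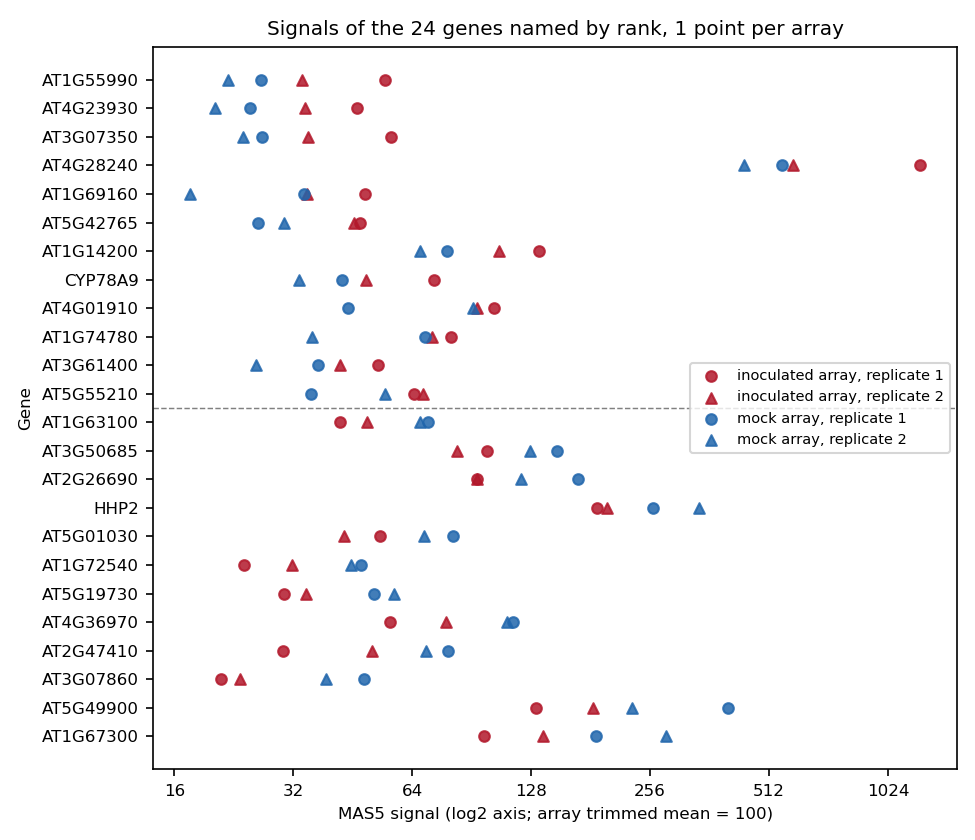
Signals of the 24 genes named by rank (rows; genes higher after inoculation above the dashed line, genes lower below it) on a log2 axis, with the array's trimmed mean scaled to 100. Each point is an array, red for inoculated and blue for mock, circles for replicate 1 and triangles for replicate 2; AT1G67300 lay at 97.4 and 137 in inoculated and at 187 and 281 in mock roots.

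The second comparison took gene groups fixed before the data were examined, starting with the homologues of genes that carry symbiotic signalling in host plants. Of the 27 members of this group, 5 were matched to a probe set and 4 were bright enough to test. The group also held genes of the strigolactone hormones such as MAX1, LysM receptor genes such as CERK1, and genes of lipid supply and secretion. These parts had no tested member, so the group result does not cover them. NSP1 (AT3G13840), a GRAS transcription factor of the symbiosis pathway in legumes, was at 49.8 and 55.9 in inoculated and 64.7 and 55.0 in mock roots, a log2 difference of -0.18 (SE 0.25). POLLUX (AT5G49960), related to the ion channels of that pathway, differed by -0.17 (SE 0.27). The nucleoporins NUP133 (AT2G05120) and NUP85 (AT4G32910), whose legume counterparts are needed for symbiotic calcium signals, differed by -0.25 (SE 0.23) and -0.01 (SE 0.24), and the sign for NUP85 turned with the scaling. NSP2 was below the filter, with signals between 9.0 and 18.1. The 4 tested members all had values below 0, 0 of them were called over all probe sets or when adjusted over the list alone, and the camera test of the group gave an adjusted p of 0.299 (adjusted p = 0.639 with an estimated correlation). The 95% intervals for NSP1 (-0.79 to 0.43), POLLUX (-0.85 to 0.51), NUP133 (-0.83 to 0.32) and NUP85 (-0.59 to 0.58) all include 0.

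Genes that respond to chitin and other microbial signals had 6 tested members of 21. ZAT10 (STZ, AT1G27730), a zinc finger repressor, was at 1161 and 1099 (inoculated) against 860 and 1139 (mock), a log2 difference of 0.19 (SE 0.23), or 0.03 after quantile normalization. The transcription factor WRKY53 differed by 0.11 (SE 0.29). The ubiquitin ligases PUB22 and PUB23, which dampen immune signalling, differed by -0.10 (SE 0.48) and -0.06 (SE 0.72), and the sign for PUB23 turned after quantile normalization. Of the 6, 4 were higher and 2 lower, 0 were called over all probe sets or adjusted over the list alone, and the camera adjusted p was 0.301 (adjusted p = 0.639 with an estimated correlation). Without the mock array of replicate 2 the list was called upward, with a camera adjusted p of 0.00492, and without the mock array of replicate 1 its direction was downward, with an adjusted p of 0.208. With all 4 arrays its adjusted p by camera or fry lay between 0.301 and 0.874. With an array left out, 1 array stands for a group, and part of the difference between replicate numbers enters that of inoculation. PUB22 and PUB23 were 1.92-fold and 3.00-fold higher in replicate 2. Of the 6 members, 0 had the same sign of difference within both replicates, so the upward call is no sign of a shared response.

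The remaining groups had few members that could be measured, and 0 members were called in any of them, over all probe sets or adjusted over the list alone. Of the salicylate group, GRX480 differed by -0.02 (SE 0.55) and SAG101 by -0.04 (SE 0.38). Of the indolic glucosinolate group, the beta-glucosidase PYK10, an abundant root protein, was at 3289 and 1865 in inoculated and 2501 and 1624 in mock roots, a log2 difference of 0.30 (SE 0.37), and UGT74B1 differed by 0.00 (SE 0.20). HCT, the only member of the phenylpropanoid group that was matched and tested, differed by 0.27 (SE 0.26). After quantile normalization the differences of PYK10 and HCT were 0.03 and 0.06. The sugar transporters SWEET2 and SWEET11 differed by -0.05 (SE 0.32) and -0.19 (SE 0.27). Of the auxin and cytokinin group, GH3.5 (WES1) differed by 0.25 (SE 0.23) and LBD16 by 0.03 (SE 0.22), and the clock gene GI differed by 0.22 (SE 0.31). Signs of GRX480, SAG101, UGT74B1 and SWEET2 turned with the scaling. The groups for phosphate starvation, jasmonate and ethylene, nitrogen, iron, sulfur, and touch, heat and drought had 0 tested members each.

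Markers of cell types that a root sample could hold in different shares were treated in the same way. The root hair expansins EXPA7 and EXPA18, which loosen cell walls, differed between inoculated and mock roots by 0.25 (SE 0.56) and 0.13 (SE 0.42). RCA, the Rubisco activase of green tissue, differed by -0.14 (SE 0.29). The groups for the root tip meristem, the xylem, and the endodermis with suberin had 0 tested members. The reference genes SAND (AT2G28390), UBC21 (PEX4) and TIP41 (AT4G34270) differed by -0.23 (SE 0.24), -0.10 (SE 0.25) and 0.01 (SE 0.29), with a camera adjusted p of 0.427 (adjusted p = 0.639 with an estimated correlation). In all, 33 of 297 members of the 20 groups were matched and 26 tested.

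The third comparison set the arrays against each other. Arrays of the same replicate number were closer to each other than arrays of the same treatment. The root mean square log2 difference over the tested probe sets was 0.36 between the inoculated and the mock array of replicate 1 and 0.22 between those of replicate 2. Between the 2 inoculated arrays it was 0.56, and between the 2 mock arrays 0.53. More than 2-fold differences were found in 202 and 22 probe sets within replicates 1 and 2, and in 965 and 724 probe sets within the inoculated and mock groups. The first principal component held 73.6% of the variance and separated replicate 1 from replicate 2. EXPA7 and EXPA18 moved with this division, at 165 and 110 (EXPA7) on the arrays of replicate 1 and at 58.0 and 61.9 on those of replicate 2. PUB22, PUB23 and GRX480 stood on the other side, with PUB23 at 71.0 and 56.1 in replicate 1 and at 161 and 223 in replicate 2.

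**Figure D2:**
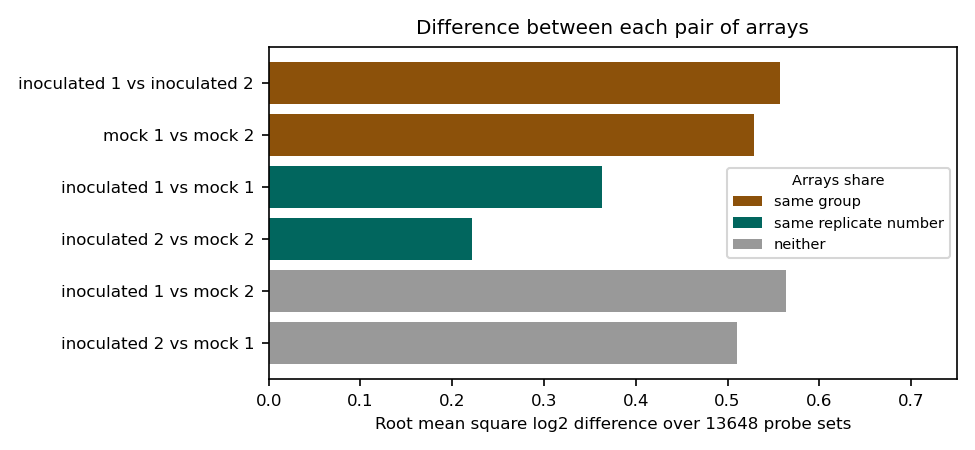
Root mean square log2 difference between each pair of arrays over the 13648 tested probe sets, coloured by what the arrays of a pair share. The pairs of the same replicate number had values of 0.36 and 0.22, and the pairs of the same group 0.56 and 0.53.

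Each way of dividing the 4 arrays into pairs was then tested alike. Dividing them by replicate number gave 2602 called probe sets with limma, 4820 at an unadjusted p under 0.05 and 1208 with a 1.5-fold gap. Dividing them by neither treatment nor number gave 0 called probe sets, 40 at an unadjusted p under 0.05 and 4 with a gap. The division by inoculation gave 0, 34 and 5.

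Brightness and control probe sets also moved with the treatment. In the brightest decile of tested probe sets, the median log2 difference between the inoculated and the mock array was 0.18 in replicate 1 and 0.07 in replicate 2, with 79.4% and 70.2% of them higher on the inoculated array. PYK10 and HCT belong to this range of signals. In the dimmest decile the medians were -0.16 and 0.00. The 18 bacterial and phage probe sets for RNA added during the procedure had medians of 0.49 and 0.67, and were higher on the inoculated array in 17 and 18 of 18 cases. They read the same few RNAs (bioB, bioC, bioD and cre) several times each, so they are not independent readings.

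**Figure D3:**
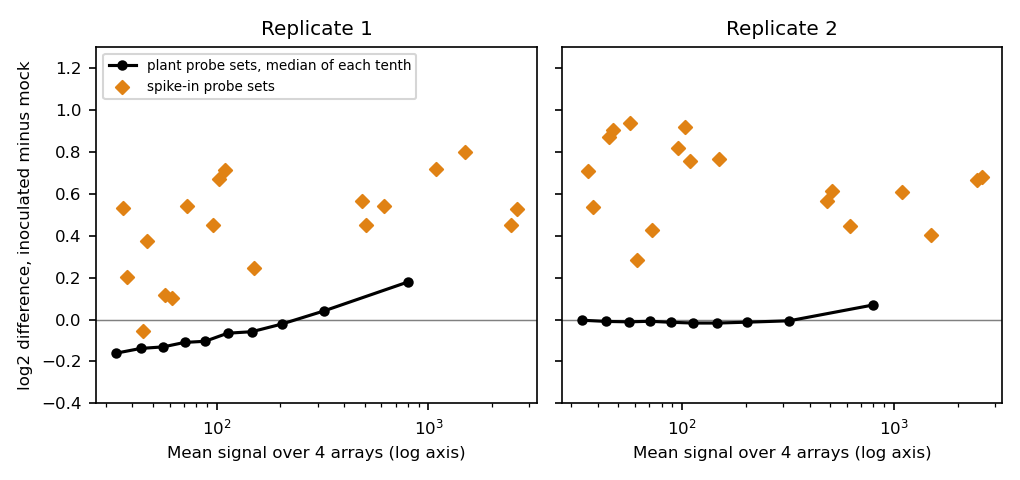
Log2 difference between the inoculated and the mock array (vertical axis) against the mean signal over the 4 arrays (log axis), for replicate 1 and replicate 2. Black points are medians of deciles of the plant probe sets, with 0.18 and 0.07 at the bright end, and orange diamonds are the 18 spike-in probe sets, with medians of 0.49 and 0.67.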

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

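The tests of the signal curve, labelled RNA, RNA degradation, ribosomal RNA, hidden effects and the other divisions were chosen after their results had been seen; those of particular abundant genes and of green tissue were written before.

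Control probe sets for RNA added during the procedure, which no comparison of plant genes uses, were brighter on the inoculated than on the mock array, by a median log2 value of 0.49 in replicate 1 and 0.67 in replicate 2. Plant probe sets in the brightest decile moved the same way, by 0.18 and 0.07. A signal curve shared by all probe sets would give the controls no excess over plant probe sets of the same brightness. Their smallest median excess was 0.44 (SD 0.21 over 18 probe sets that share a few RNAs), which argues against that curve alone for the controls. For the plant probe sets the curve stays open, since a changed ratio of control to plant RNA would also lift the controls off it. Particular abundant genes raised by inoculation, if many and alike in both replicates, would tend to correlate between the replicates. The differences of the brightest decile, after quantile normalization, had r = -0.20 across 1365 probe sets (95% bootstrap interval -0.26 to -0.13, genes are not independent replicates). Each difference rests on 1 pair of arrays, whose errors can lower r. A few raised genes would hardly move r, so this value cannot decide on them. Less labelled plant RNA on the inoculated arrays may account for the controls, of which at least 94.4% were brighter there, but it cannot be told apart from other causes for the plant probe sets, since the larger control shift was in replicate 2 and the larger plant shift in replicate 1.

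The control probe set for 25S ribosomal RNA, also outside the comparisons, had a signal of 2005 on the inoculated and 1239 on the mock array of replicate 2, against 27.9 and 11.4 in replicate 1, and so followed the division of the arrays by replicate number, in which 2602 probe sets were called. The dim control probe set for 5S ribosomal RNA did not follow it, at 11.3 (inoculated) and 14.4 (mock) in replicate 2 and 6.95 and 18.4 in replicate 1. Ribosomal RNA diluting the labelled sample would lower all plant transcripts by one factor, which the scaling of each array removes. Yet 280 called probe sets were at least 2-fold higher in replicate 1 and 336 at least 2-fold higher in replicate 2. These argue against dilution alone as the source of the called probe sets, but cannot tell whether the samples were also diluted. RNA degradation would move the ratios of 3' to 5' signal of actin, GAPDH and ubiquitin together, but only 1 of the 3 differed in the direction of actin (log2 -0.35, replicate 1 minus 2) by more than within a number, actin itself, and GAPDH differed the other way (0.26, against at most 0.17 within a number). The actin ratio was 7.30 (inoculated) and 6.12 (mock) in replicate 1, and 9.20 and 7.86 in replicate 2. GAPDH lay between 1.15 and 1.49 and ubiquitin between 1.80 and 2.72. A 3' bias shared by all arrays would not show in this comparison and stays a limit of the data. Green tissue could move the plastid-encoded genes together. Their median difference was -0.031 over 46 genes, with 5 called higher and 7 called lower in replicate 1, where 19.1% of all tested probe sets were called. This cannot decide on green tissue, since the 46 include genes of plastid ribosomes and RNA polymerase, such as rps3, rpl32 and rpoA, which are no markers of it. A difference between the replicates in plants, growth or array processing stays open and was not tested, since the labels do not say what the number marks.

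The absence of called probe sets for inoculation was weighed against the large spread between replicate numbers. If that spread hid large effects on many genes, alike in both replicates, the differences measured within the replicates would tend to correlate above 0. They had r = -0.078 and rho = -0.069 across 13648 probe sets, and r = -0.11 after quantile normalization. Each difference rests on 1 pair of arrays, whose errors can lower r, so modest shared effects on many genes are not excluded. The 4 arrays have 3 splits into pairs, too few for a share under 0.05. The real split had 0 calls and the highest other, by replicate number, had 2602, which points to a structure of the samples. The limma fit with the replicate number as a block, which takes that spread out, called 0 probe sets (lowest adjusted p = 0.998). On simulated data it found 69.3% of 2-fold and 99.6% of 4-fold changes, though with too many false calls. At least 1.5-fold, 5 probe sets were higher and 14 lower in both replicates, and 30 went in opposite directions. These values argue against large effects shared by both replicates in many tested probe sets. Effects on few genes, small ones, or ones present in 1 replicate stay open.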

How the results depend on the processing

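The block and its combination with quantile normalization concern a replicate number that may be only a number: the same-numbered arrays deviate together (r = 0.68 across probe sets), but with 2 pairs and no label for what the number marks, this is a hint from the data. The combination was chosen after seeing the data. The count of 0 called probe sets was the same under every alternative run, the replicate block included, with lowest adjusted p between 0.766 and 1. The 34 probe sets at an unadjusted p under 0.05 became 389 without a filter, 15 with the filter at the 60th percentile, 434 (233 higher, 201 lower) with the replicate block, and 400 (207 and 193) with the replicate block and quantile normalization. They ranged from 31 to 354 with an array left out, where the lone array is assumed to vary like the others; the counts were 354 without inoculated replicate 2 and 132 without mock replicate 2, and of the 34, 16 and 11 recurred. Without inoculated replicate 1 and mock replicate 1, 1 and 3 of the 34 recurred, and the latter gave 19 higher and 12 lower. Quantile normalization turned the division of 6 higher and 28 lower into 13 and 17, and median centring into 9 and 20. The 5 probe sets with a 1.5-fold gap became 385 without a filter, 0 with the offset, 0 with the filter at the 60th percentile and 0 with a 2-fold gap. For the 1.5-fold gap, fewer or more dim probe sets account for the filter's part by construction. For the unadjusted p the fit was also redone on the new set, and without a filter 23 of the 34 recurred. For the rest the cause was not tested. The number of called lists, 0, ranged from 0 to 1 with an array left out: without mock replicate 2 the chitin and defence list was called. The lowest adjusted p of a list was 0.00492 there and between 0.208 and 0.717 under the others. In the fits of lists with an array left out, part of the difference between replicate numbers also enters that of inoculation. The eBayes options do not enter camera and were not run for lists. Same-group over same-number array distance was 1.86, and 1.27 without a filter and 2.05 at the 60th percentile. The median 95% interval of a log2 difference reached 0.41 to either side with the block and 0.66 without. MAS5 signal near background limits the dim probe sets.

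The rule that named the 24 genes by rank largely fixes their sign under these alternatives, so it is no check of them. The list examples changed sign in 48 of 305, and none passed the threshold. With an array left out, their differences take in part of the difference between replicate numbers, which was large for EXPA7 and PUB23. After quantile normalization, with and without the block, NUP85 (AT4G32910) was at 0.0486, PUB23 at 0.00599, SAG101 at 0.0259, GRX480 at 0.0392, UGT74B1 at -0.00829 and SWEET2 at 0.0333; after median centring NUP85 was at 0.0465, SAG101 at 0.0113, GRX480 at 0.0297 and SWEET2 at 0.00145. With an array left out, the log2 differences ranged from -0.38 to 0.0440 for POLLUX (AT5G49960), from -0.17 to 0.16 for NUP85, from -0.76 to 0.56 for PUB22, from -1.06 to 0.93 for PUB23, from -0.10 to 0.32 for WRKY53, from -0.0120 to 0.39 for ZAT10, from -0.52 to 0.44 for SAG101, from -0.81 to 0.76 for GRX480, from -0.11 to 0.13 for UGT74B1, from -0.11 to 0.71 for PYK10, from -0.47 to 0.0856 for SWEET11, from -0.36 to 0.25 for SWEET2, from -0.0650 to 0.12 for LBD16, from -0.14 to 0.59 for GI, from -0.41 to 0.67 for EXPA18, from -0.51 to 1.00 for EXPA7, from -0.41 to 0.14 for RCA, from -0.31 to 0.11 for UBC21 and from -0.28 to 0.30 for TIP41 (AT4G34270).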

Other observations

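The genes in this paragraph were chosen after their values were seen, from those called with limma between the arrays of replicate 1 and replicate 2, each with 1 inoculated and 1 mock array. The chitinase CHI (AT2G43570) was at 254 and 262 in replicate 1 and at 38.2 and 35.5 in replicate 2, a 7.0-fold difference (log2 2.81, SE 0.14). OSM34, an osmotin-like protein, was 4.58-fold higher and the chitinase ChiC 4.56-fold higher, though ChiC had 68.1 on the inoculated and 142 on the mock array of replicate 1. The cell wall genes HRGP1, a hydroxyproline-rich extensin, and EXPA7, an expansin of root hairs, were 3.08-fold and 2.24-fold higher, and both tested members of the root hair group were called in this direction. The dehydrin LTI30, linked to cold and drought, was at 651 and 1574 in replicate 1 and at 347 and 366 in replicate 2. Of the fixed chitin and defence list, 0 of 6 tested members were called higher in replicate 1, and PUB22 and PUB23 were called higher in replicate 2 (camera adjusted p = 0.253, and adjusted p = 0.717 with an estimated correlation). CHI, OSM34, ChiC, HRGP1, EXPA7 and LTI30 kept their direction after quantile normalization.

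The genes named next, also chosen after their values were seen, were called higher in replicate 2. The calmodulin-like gene CML38 was at 187 and 222 in replicate 2 and at 75.0 and 38.5 in replicate 1, and CML37 and CML23 differed by 2.87-fold and 2.31-fold. ORA47, a transcription factor of jasmonate responses, differed by 3.61-fold, PUB23 by 3.00-fold, and GRX480, a salicylate-responsive glutaredoxin, by a log2 value of -1.11 (replicate 1 minus 2). The subunits of a splicing factor, ATU2AF35A and U2AF35B, differed by 3.98-fold and 3.48-fold. The nitrate transporter NRT2.5 was at 273 and 210 against 80.9 and 115, and FATB, a thioesterase of fatty acid synthesis, at 521 and 508 against 152 and 212. With quantile normalization 2734 probe sets were called, of which 2352 were among the 2602. With inoculation as a further term 2175 were called. No family of the 13 tested by camera was called, for inoculation (lowest adjusted p = 0.429) or for the replicate number (lowest adjusted p = 0.216). Among 21 UDP-glycosyltransferases, 5 were called higher in replicate 2 and 0 in replicate 1 (camera adjusted p = 0.236, and adjusted p = 0.584 with an estimated correlation), among them UGT72E2 at 842 and 757 against 358 and 442. Of 7 SWEET sugar transporters and of 11 glutathione S-transferases, 2 each were called higher in replicate 1 and 0 in replicate 2 (camera adjusted p = 0.216 and 0.365). Over all 13648 tested probe sets, 1054 were called higher in replicate 1 and 1548 in replicate 2.

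The differences between inoculated and mock arrays were compared between the replicates. In replicate 1, 324 probe sets were at least 1.5-fold higher and 858 at least 1.5-fold lower after inoculation, and in replicate 2 these counts were 138 and 144. After quantile normalization they were 480 and 519 in replicate 1 and 142 and 133 in replicate 2, so the lower-side excess of replicate 1 depends on the scaling. With the deposited scaling, 5 were higher in both and 14 lower in both, where independent lists would give 3.28 and 9.05, and 30 went in opposite directions, where independent lists would give 12.1. After quantile normalization 14 were higher in both, 8 lower in both and 25 opposite, where independent lists would give 4.99, 5.06 and 10.1. These figures assume that every probe set is equally likely to pass 1.5-fold, which noisy dim probe sets would break. Since the opposite overlaps exceeded them too, the excess of 14 is no sign of a shared response on its own.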
